A study of Homo sapiens with 16 samples.

How the data were processed

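Poly(A) RNA was sequenced from HaCaT cells, a spontaneously immortalised line of human keratinocytes. The cells were either a CRISPR/Cas9 knockout of REDD1, the protein product of the gene DDIT4, or control cells that had received Cas9 only, written here as KO and WT. Both kinds of cells were left with vehicle, given 1 µM fluocinolone acetonide (FA, a synthetic glucocorticoid), wounded by scratching the cell layer, or wounded and given FA, and were harvested after 24 h. Each of the 8 groups held 2 libraries, 16 in all. The labels did not say whether the libraries of a group came from separate cultures, so each p-value measures the spread between these samples, which may be technical. The labels also did not say whether the knockout was a single clone or a pool.

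Per the labels' protocols, libraries were made with a stranded TruSeq kit and sequenced paired-end on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools named were cutadapt 1.10, FastQC 0.10.1, HISAT2 2.0, StringTie 1.3 and edgeR. Their settings were not given in the sources used here. Per the file headers, the authors gave each gene an estimated count and an FPKM value in each library. The deposited counts were unnormalised whole numbers and were taken as estimated counts, because StringTie was the only quantifier named. The deposited FPKM values were scaled by the authors to gene length and library size, and the entries with a count of 0 were listed at an FPKM of 0.0001. The role of strand in the counting was not stated, so overlapping genes and near-identical copies are reported as uncertain. The genome build was not stated either. Of 58825 genes in the table, 58552 had an identifier in the GENCODE 29 annotation of GRCh38, and 99.997% of these overlapped the gene of that annotation, so coordinates are given as GRCh38.

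Estimated counts summed to between 50462958 and 74334868 per library. Replicate 1 libraries held 50462958 to 63121666 and replicate 2 libraries 66405268 to 74334868, so replicate number and depth went together. The libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 61.07 in every group, and were kept as separate samples. A count of 0 allows up to 3 counts, and intervals and floors cover counting error only.

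Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust estimation, TMM scaling and 1 mean for each of the 8 groups. Genes were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 21896 genes, and p-values were adjusted by the Benjamini-Hochberg method over these genes at a threshold of 0.05. Below, a gene is called when it passed that threshold, and each adjusted p of a gene comes from edgeR's quasi-likelihood test. All fold changes are on the log2 scale and are given ± the standard error of the model, from 2 libraries per group. Means over the 4 treatments, and over the 4 FA or wound contrasts, were contrasts in the same fit.

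Gene lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over the 33 lists. The lists held 739 genes, of which 708 were tested. They covered glucocorticoid, inflammatory, keratinocyte, wound, growth, stress and metabolic genes, markers of other cell types, and mitochondrial and histone RNAs as signs of RNA quality. The genes named were DDIT4 in every library, then, for each comparison, the 8 called genes with the largest rise and the 8 with the largest fall. These needed an official symbol and a mean of at least 5 FPKM in the higher condition, or in any group of the contrast for differences between effects. For each list, up to 4 called members with the smallest p were named, or up to 2 members given as values where none was called. The groups, comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined; the means of the differences between KO and WT were added after the data were seen.

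Whether equal replicate numbers paired the samples was checked from the correlation of deviations from the group means. All 28 pairs of groups had a correlation of 0.163 or more, up to 0.377, and the principal component that carried 14.7% of the variance separated replicate 1 from replicate 2. The numbers therefore paired the samples, and the value with replicate as a block is given where it changed a call or moved a count by over 1.5 times. The pairing came from the values and not from a statement in the labels. Other alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) with a minimum of 1 FPKM in 2 libraries, a fit of the compared groups alone, and leaving out each library. In a fit with 1 library left in a group, that library was assumed to vary like the other groups. Those fits also tested more genes, 23355 to 23690, because the filter on low counts depends on group size. A count or call lost there therefore cannot be put down to the library left out alone.

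The tests were also run, after the main fit, on simulated counts with known fold changes. These were drawn from the means, spread and library sizes of the main fit for the 21896 genes. Each simulated library varied independently, with no shift shared by equal replicate numbers. Figures were drawn with Python 3.11.15. Differences between cell lines that were not measured, such as DNA copy number, were not analysed here.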

Results

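The transcriptomes of REDD1 knockout (KO) and Cas9-only control (WT) HaCaT keratinocytes were compared with vehicle, with 1 µM of the glucocorticoid FA, after a scratch wound, and after a wound with FA, all at 24 h. The question named by the study's title was how loss of REDD1 alters the transcriptional response to wounding and to a glucocorticoid. REDD1 is a stress-inducible inhibitor of mTOR complex signalling, and its gene DDIT4 is itself induced by glucocorticoids. Each of the 8 groups had 2 libraries, with 50462958 to 74334868 estimated counts per library. The first principal component, with 34.3% of the variance, separated KO from WT, and the component with 8.51% separated FA from no FA.

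The transcript of the targeted gene was lower in KO but was still present in every KO library. DDIT4 (ENSG00000168209; GRCh38 chromosome 10, 72273924 to 72276036, plus strand) measured 74 ± 45.8 FPKM in WT with vehicle (SD, n = 2) and 30.4 ± 15.3 FPKM in KO with vehicle (SD, n = 2). With FA, DDIT4 measured 170.8 ± 34.3 FPKM in WT and 56.7 ± 13.3 FPKM in KO. After wounding it measured 82.4 ± 38.5 FPKM in WT and 30.9 ± 16.1 FPKM in KO, and after wounding with FA 167.2 ± 39.8 FPKM in WT and 59.9 ± 14.2 FPKM in KO.

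In single libraries with vehicle, DDIT4 was at 41.6 and 106.4 FPKM in WT and at 19.6 and 41.2 FPKM in KO. With FA the DDIT4 values were 146.6 and 195.0 FPKM in WT and 47.2 and 66.1 FPKM in KO. After wounding the DDIT4 values were 55.2 and 109.6 FPKM in WT and 19.5 and 42.3 FPKM in KO, and with both they were 139.0 and 195.3 FPKM in WT and 49.9 and 69.9 FPKM in KO. Replicate 1 was the lower library in all 8 groups. Over the 4 treatments DDIT4 fell by 1.47 ± 0.24 in KO (adjusted p = 0.000547 in edgeR's quasi-likelihood test), and an exact two-sided permutation test within treatments gave p = 0.00154 over 1296 arrangements. In single treatments DDIT4 was called under FA alone (adjusted p = 0.0405; vehicle 0.0988, wound 0.0647, wound with FA 0.0509). With replicate as a block it was called in all 4, with vehicle at an adjusted p of 0.00251. A remaining transcript does not show whether protein was made; protein was not analysed here.

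**Figure D1:**
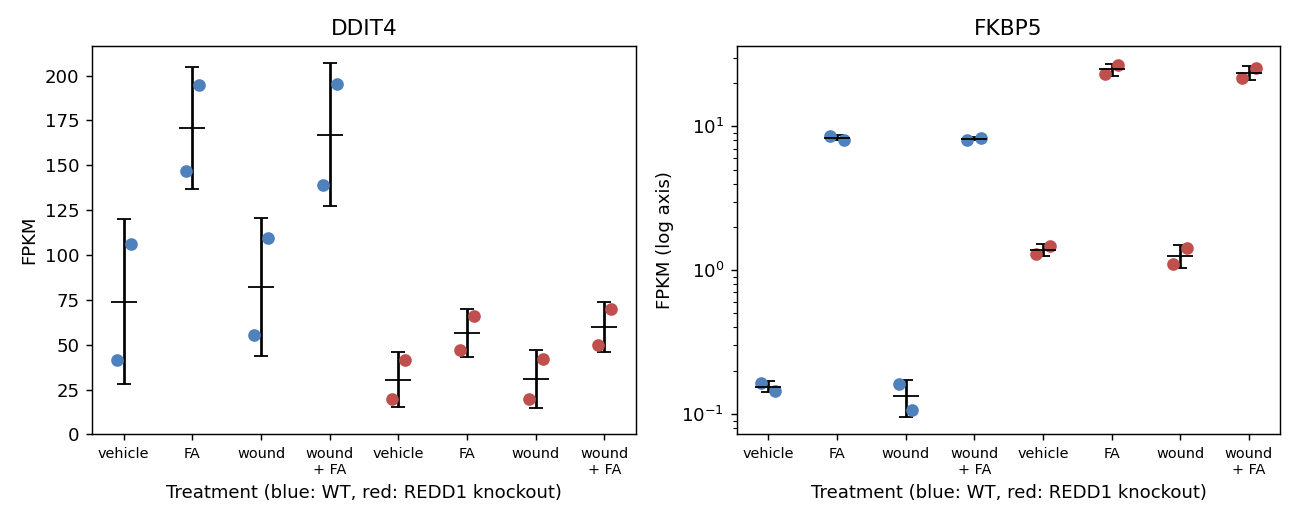
DDIT4 (linear axis) and FKBP5 (log axis) in FPKM in each library by treatment, WT in blue and KO in red; horizontal lines are means and bars are ± 1 SD of 2 libraries. Mean DDIT4 was 74 FPKM in WT and 30.4 FPKM in KO with vehicle, and mean FKBP5 was 0.155 FPKM in WT and 1.39 FPKM in KO.

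KO and WT differed in the levels of a large part of the tested genes. Averaged over the 4 treatments, CALB2, a calcium-binding protein, was higher in KO by 5.15 ± 0.23 (53.3 against 1.69 FPKM; adjusted p = 9.22e-08), and TFPI2, a protease inhibitor, by 3.86 ± 0.52 (adjusted p = 0.000175). The matrix glycoprotein TNC fell by 4.92 ± 0.34 (0.700 against 20.8 FPKM; adjusted p = 1.7e-06), the collagenase MMP13 fell by 4.71 ± 0.33 and MYL9, a myosin light chain, fell by 4.70 ± 0.37. The stress keratin KRT17 (chromosome 17, 41619441 to 41624708, minus strand) fell by 3.01 ± 0.14 (adjusted p = 3.84e-08), with 1141 ± 433 FPKM in WT and 143.7 ± 17.6 FPKM in KO with vehicle (SD, n = 2).

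Of the 21896 genes tested, edgeR called 10599 for the mean of the 4 treatments, 5341 higher and 5258 lower in KO. The balance of directions depended on the measure and the genes tested. By at least 2-fold, 1209 of the called genes were higher and 2152 lower. Limma on log2(FPKM + 1), without TMM scaling and with 12857 genes tested, called 4471 higher and 3379 lower. Other large rises were those of CYP4F11 (3.12 ± 0.09), a fatty acid hydroxylase, A2ML1 (3.02 ± 0.32), GDPD2 (2.91 ± 0.31), NT5E (2.87 ± 0.30), the ecto-nucleotidase CD73, GNG4 (2.41 ± 0.41) and SERPINB1 (2.38 ± 0.28). Other large falls were those of LINC02518 (-5.38 ± 0.54), the phospholipase PLA2G2A (-5.16 ± 0.46), the estrogen sulfotransferase SULT1E1 (-4.88 ± 0.31), LGALS7B (-4.82 ± 0.24) and SEMA6D (-4.71 ± 0.17). LGALS7B has a near-identical copy, LGALS7, and its value is uncertain for that reason. Of the 10599 genes, 10321 (97.4%) had the same sign in all 4 treatments, but they were selected for their mean over these treatments, which favours equal signs. Over all tested genes the differences in 2 treatments correlated by 0.503 to 0.535 across genes, which are not independent replicates.

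Cell cycle genes formed the group with the most uniform rise: 42 of 46 measured members were higher, 0 were lower and 4 did not pass, and 45 passed when adjusted over the list alone. RRM2, a ribonucleotide reductase subunit, rose by 1.60 ± 0.16, the centromere histone CENPA by 1.48 ± 0.17, and the replication factor CDC45 by 1.47 ± 0.18. The list was called up by camera (adjusted p = 5.74e-11; adjusted p = 0.81 with an estimated correlation). Glycolysis genes were higher in 10 of 18 and lower in 2 (12 adjusted over the list alone), among them GAPDH (1.03 ± 0.07), ALDOA (0.74 ± 0.06) and LDHA (0.74 ± 0.08), with a camera adjusted p of 0.00667 (adjusted p = 0.81 with an estimated correlation). Heat shock genes were higher in 10 of 13 and lower in 1 (11 adjusted over the list alone), among them DNAJA1 (0.84 ± 0.12) and BAG3 (0.51 ± 0.06), with a camera adjusted p of 0.00667 (adjusted p = 0.81 with an estimated correlation).

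Basal keratinocyte and adhesion genes were lower in 21 of 25 and higher in 0, with 21 adjusted over the list alone. NOTCH1 fell by 0.95 ± 0.07, the growth factor receptor EGFR fell by 1.12 ± 0.09, the laminin chain LAMA5 fell by 0.77 ± 0.08, and camera called the list down (adjusted p = 5.29e-06; adjusted p = 0.81 with an estimated correlation). TGF-beta targets were lower in 14 of 22 and higher in 2 (17 adjusted over the list alone), among them the actin-binding protein TAGLN (-3.03 ± 0.14) and the collagen chains COL4A1 (-0.88 ± 0.07) and COL4A2 (-1.03 ± 0.09). Camera called this list down (adjusted p = 3.94e-05; adjusted p = 0.0606 with an estimated correlation). The list of epithelial-mesenchymal transition and matrix genes had 11 of 27 lower and 7 higher (18 adjusted over the list alone), among them MMP2 (-2.21 ± 0.10) and COL5A1 (-3.41 ± 0.24). Its camera adjusted p was 0.00667 (adjusted p = 0.81 with an estimated correlation) and 0.111 with replicate as a block.

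ATF4 and amino acid response genes were lower in 14 of 31 and higher in 4 (19 adjusted over the list alone), led by NUPR1 (-4.10 ± 0.33). Camera did not call this list (adjusted p = 0.0712), but did with replicate as a block (adjusted p = 0.00354; adjusted p = 0.891 with an estimated correlation). The mitochondrially encoded mRNAs, kept as a sign of RNA quality, were lower in 4 of 13 and higher in 0 (4 adjusted over the list alone), among them MT-CO1 (-0.76 ± 0.11). They were called with replicate as a block alone (adjusted p = 0.00102; without it 0.16; adjusted p = 0.891 with an estimated correlation). Mitochondrial RNA took 7.48 ± 1.21% of the counts in KO and 11 ± 2.07% in WT (SD, n = 8), a difference that passed an exact two-sided permutation test within treatments (p = 0.00617). The ranges overlapped, at 5.91 to 9.24% in KO and 8.83 to 13.2% in WT. In every group the share was higher in replicate 1 than in replicate 2, such as 13.08 against 8.83% in WT with vehicle. Whether the share went with the KO gene groups described here was not tested.

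The other lists were not called by camera for KO against WT, though many members changed in both directions. Of all tested genes 48.4% were called for this contrast, so member counts near that share do not set a list apart. Interferon-stimulated genes were higher in 14 of 30 and lower in 7 (21 adjusted over the list alone), with USP18 at 2.21 ± 0.11. The p53 targets were higher in 13 of 25 and lower in 7 (21 adjusted over the list alone), and PI3K-AKT-mTOR components, the pathway REDD1 acts on, were higher in 14 of 31 and lower in 8 (22 adjusted over the list alone), with MTOR at -0.56 ± 0.05. The median and the mean of the PI3K-AKT-mTOR list, 0.15 and -0.06, differed in sign. Cytosolic ribosomal proteins were higher in 19 of 38 and lower in 6 (26 adjusted over the list alone), and NRF2 targets were higher in 9 of 24 and lower in 5 (14 adjusted over the list alone).

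Glucocorticoid receptor targets were lower in 12 of 28 and higher in 2 (14 adjusted over the list alone), and FKBP5 was higher at 2.34 ± 0.09. Wound-edge genes were lower in 13 of 37 and higher in 9 (22 adjusted over the list alone), suprabasal differentiation genes lower in 15 of 51 and higher in 8 (23 adjusted over the list alone), and YAP/TAZ targets lower in 8 of 22 and higher in 5 (13 adjusted over the list alone). Inflammatory cytokines were lower in 5 of 19 and higher in 3 (8 adjusted over the list alone), with CCL2 at -5.05 ± 0.42, and other NF-kB pathway genes were higher in 6 and lower in 6 of 27 (11 adjusted over the list alone). Immediate early genes were higher in 6 and lower in 4 of 26 (10 adjusted over the list alone), unfolded protein response genes higher in 6 and lower in 5 of 22 (11 adjusted over the list alone), and hypoxia targets lower in 10 and higher in 5 of 27 (15 adjusted over the list alone).

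Autophagy and lysosome genes were lower in 8 and higher in 5 of 23 (14 adjusted over the list alone), cholesterol synthesis genes lower in 8 and higher in 2 of 25 (10 adjusted over the list alone), and fatty acid genes lower in 8 and higher in 7 of 25 (17 adjusted over the list alone). Nuclear receptor genes were higher in 8 and lower in 5 of 20 (13 adjusted over the list alone), clock genes higher in 4 and lower in 3 of 16 (7 adjusted over the list alone), and metallothioneins higher in 1 and lower in 1 of 6 (2 adjusted over the list alone). Among signs of RNA quality and other cell types, replication-dependent histones were lower in 4 and higher in 0 of 10 (4 adjusted over the list alone), and fibroblast markers lower in 4 and higher in 2 of 7 (6 adjusted over the list alone). Melanocyte markers were lower in 2 and higher in 0 of 4 (2 adjusted over the list alone), immune markers higher in 3 and lower in 1 of 6 (4 adjusted over the list alone), and endothelial markers higher in 1 and lower in 0 of 4 (1 adjusted over the list alone). The median and the mean also differed in sign for the fatty acid, unfolded protein response, hypoxia, NRF2, nuclear receptor and immune lists. Camera ranked the cytokine list down, against a median of 0.00467 and a mean of 0.0344, without calling it.

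**Figure D2:**
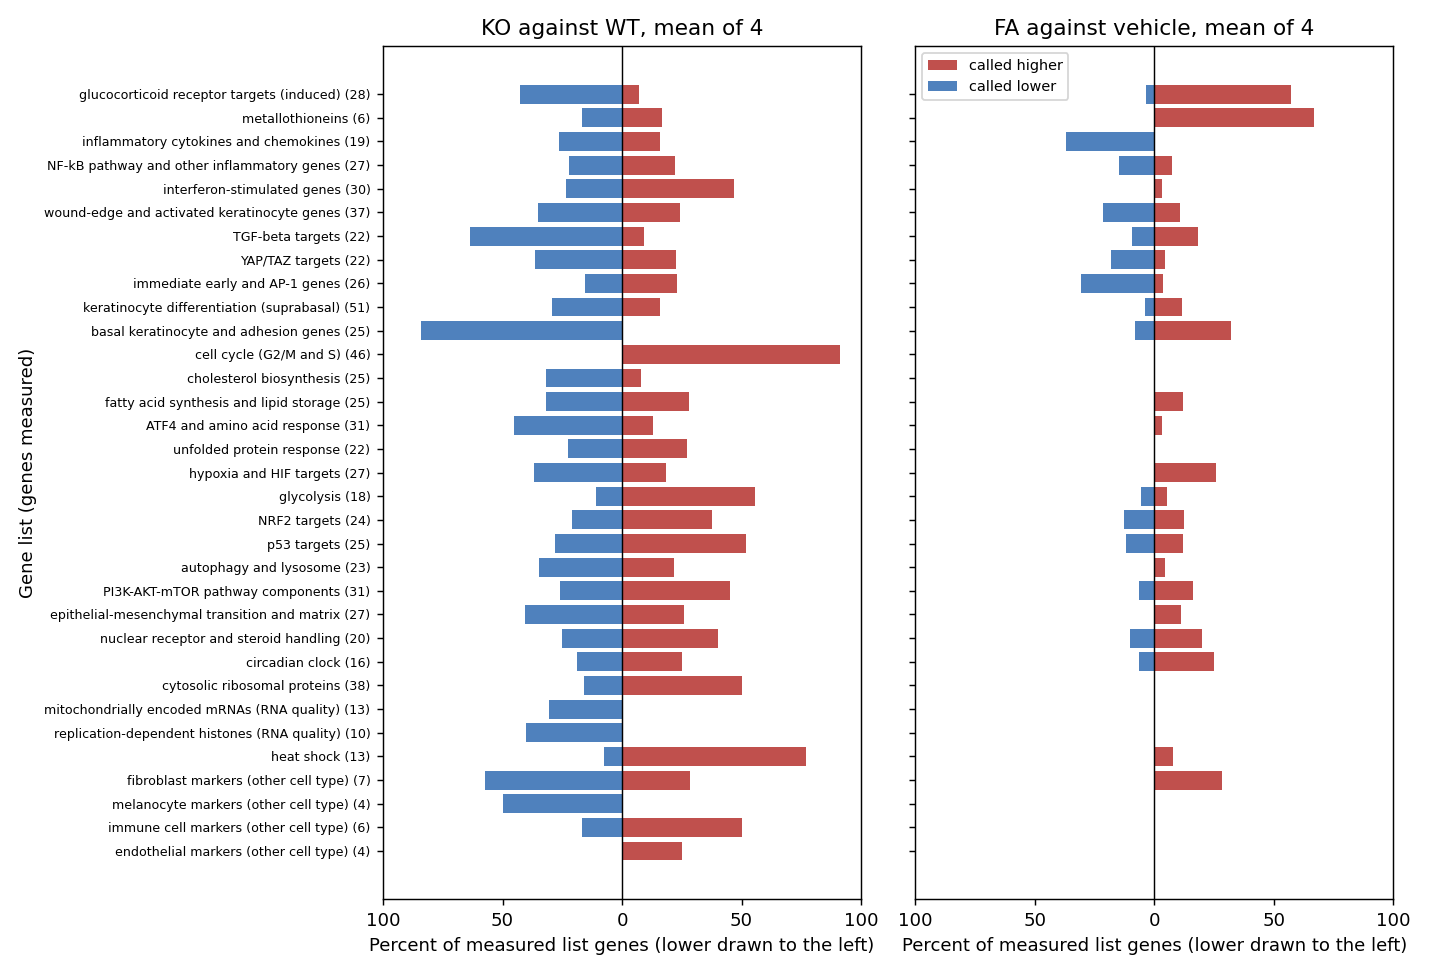
Percent of the measured genes of each of the 33 lists called higher (red, to the right) or lower (blue, to the left) for KO against WT and for FA against vehicle, each the mean of 4 contrasts; numbers in brackets are genes measured. In KO against WT, 42 of 46 cell cycle genes were called higher and 21 of 25 basal genes lower; with FA, 16 of 28 glucocorticoid receptor targets were called higher.

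Within single treatments, CALB2 was higher in KO by 4.38 ± 0.44 with vehicle, by 5.55 ± 0.48 with FA, by 4.75 ± 0.45 after wounding and by 5.91 ± 0.49 after wounding with FA. MYL9 was lower in each, at -4.71 ± 0.74, -4.57 ± 0.74, -4.79 ± 0.75 and -4.75 ± 0.75. RAB43, with the largest fitted rise in vehicle (7.86 ± 1.96), overlaps another gene on its strand and is uncertain. Beyond the genes already named, the rule named in single treatments SH3KBP1, ERCC5, SLX1B, UMAD1 and USP18 among rises and CYP24A1, MPPED2, PSG5, CLDN8 and LGALS7 among falls, with CYP24A1 at -5.01 ± 0.58 and MPPED2 at -4.04 ± 0.36 with vehicle.

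The counts of called genes were 3548 with vehicle (1809 higher, 1739 lower; 5330 with replicate as a block), 4395 with FA (2337 higher, 2058 lower), 3892 after wounding (1972 higher, 1920 lower) and 4730 after wounding with FA (2496 higher, 2234 lower). By at least 2-fold, in the same order, 508, 658, 553 and 770 were higher and 899, 1080, 986 and 1158 lower. Limma, with 12857 genes tested and no TMM scaling, tipped the other way, with 1606, 2161, 1927 and 2195 higher and 1266, 1408, 1245 and 1611 lower. Called in all 4 treatments were 1252 higher and 1158 lower genes. Vehicle and FA shared 1499 higher genes (193 expected from independent lists) and 1375 lower genes (163 expected), from separate libraries. In a fit of the compared groups alone, 980 genes were called with vehicle, 860 after wounding and 3127 after wounding with FA.

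The single-treatment counts were lower whichever library was left out, in fits with 1 library left in a compared group and more genes tested. They therefore do not single out a library. With vehicle the count was 1745 without KO replicate 1, 1628 without KO replicate 2 and 1474 without WT replicate 2. With FA it was 2181 and 2185 without KO replicates 1 and 2, and 2157 and 2830 without WT replicates 1 and 2. After wounding it was 1694 and 2455 without KO replicates 1 and 2, and 1662 without WT replicate 2; after wounding with FA it was 3100 and 2170 without KO replicates 1 and 2, and 2741 and 2238 without WT replicates 1 and 2. The count for the mean of the 4 treatments stayed between 9762 and 10383.

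FA raised well-known glucocorticoid-induced genes in both kinds of cells. Averaged over genotype and wounding, FKBP5 (ENSG00000096060; chromosome 6, 35573585 to 35728583, minus strand), a co-chaperone of the glucocorticoid receptor, rose by 5.05 ± 0.10 (adjusted p = 6.27e-11). TSC22D3, which encodes the glucocorticoid-induced leucine zipper, rose by 3.32 ± 0.14 (adjusted p = 1.17e-07) and SULT1E1 rose by 4.53 ± 0.31. CYP24A1, the vitamin D 24-hydroxylase, fell by 3.05 ± 0.28 (adjusted p = 7.39e-05), and the chemokines CXCL8 and CXCL1 fell by 2.72 ± 0.61 and by 1.93 ± 0.34. DDIT4 rose by 1.08 ± 0.24 (adjusted p = 0.0207 in edgeR's test). In single FA contrasts edgeR did not call DDIT4 (adjusted p from 0.392 to 0.845), but with replicate as a block it called DDIT4 in WT (adjusted p = 0.00889), wounded WT (0.027) and wounded KO (0.0467), and not in KO (0.0614).

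In all, 1857 genes were called for the mean FA effect, 920 higher and 937 lower, and 3015 with replicate as a block (1384 higher, 1631 lower). The balance of directions depended on the measure and the genes tested. Limma on log2(FPKM + 1), without TMM scaling and with 12857 genes tested, called 583 higher and 1033 lower. Of the 1857 genes, 284 were higher and 105 lower by at least 2-fold. Further large rises were those of TFCP2L1 (3.79 ± 0.22), the costimulatory ligand CD86 (3.52 ± 0.30), TMEM63C (3.14 ± 0.19), FLRT3 (2.71 ± 0.19) and RGS2 (2.70 ± 0.15). Further large falls were those of PHLDA1 (-2.13 ± 0.45), MMP13 (-1.85 ± 0.30), the hyaluronan synthase HAS3 (-1.58 ± 0.21), the protease PLAU (-1.38 ± 0.17) and the AP-1 subunit FOSL1 (-1.35 ± 0.36). FOSL1 had an adjusted p of 0.0497 in edgeR's test and of 0.0728 with replicate as a block.

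Glucocorticoid receptor targets were higher in 16 of 28 and lower in 1, with 22 adjusted over the list alone; besides FKBP5 and TSC22D3, NFKBIA, an inhibitor of NF-kB, rose by 1.37 ± 0.08. PER1, listed in the table as AC129492, rose by 3.64 ± 0.13. Camera called the list up (adjusted p = 2.33e-70; adjusted p = 1.15e-05 with an estimated correlation). Metallothioneins, metal-binding proteins, were higher in 4 of 6 and lower in 0 (5 adjusted over the list alone), with MT2A at 1.81 ± 0.08 and MT1E at 1.99 ± 0.10 (camera adjusted p = 2.52e-36; adjusted p = 0.00159 with an estimated correlation). Nuclear receptor and steroid handling genes were higher in 4 of 20 and lower in 2 (9 adjusted over the list alone), with HSD11B2, which inactivates cortisol, at 1.40 ± 0.14; camera called it up (adjusted p = 7.88e-05; adjusted p = 0.0153 with an estimated correlation). It did not with replicate as a block (adjusted p = 0.396), and the list's median, -0.01, and mean, 0.24, differed in sign.

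PI3K-AKT-mTOR components were higher in 5 of 31 and lower in 2 (7 adjusted over the list alone). Their largest change was that of FKBP5, also a member, and IRS1, an insulin receptor substrate, was lower at -1.43 ± 0.22. Camera called this list up (adjusted p = 0.00347; adjusted p = 0.0403 with an estimated correlation). It did not with replicate as a block (adjusted p = 0.554), and the list's median, -0.03, and mean, 0.15, differed in sign. The clock list was higher in 4 of 16 and lower in 1 (8 adjusted over the list alone), with CIART at 2.37 ± 0.16 and CLOCK at -0.36 ± 0.08 (camera adjusted p = 5.82e-06; adjusted p = 0.0629 with an estimated correlation).

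Inflammatory cytokines and chemokines were lower in 7 of 19 and higher in 0 (8 adjusted over the list alone). CXCL6 fell by 2.28 ± 0.31, CCL2 fell by 2.74 ± 0.44 and IL23A fell by 1.53 ± 0.32, and camera called the list down (adjusted p = 1.76e-07; adjusted p = 0.0629 with an estimated correlation). Immediate early and AP-1 genes were lower in 8 of 26 and higher in 1 (10 adjusted over the list alone); IER3 was lower at -1.15 ± 0.16 and FOSL2 higher at 1.47 ± 0.06 (camera adjusted p = 0.0382; adjusted p = 0.843 with an estimated correlation). Wound-edge genes were lower in 8 of 37 and higher in 4 (14 adjusted over the list alone); the stromelysin MMP3 was lower at -5.17 ± 0.46, and the keratin KRT6A was higher at 0.84 ± 0.07 (camera adjusted p = 0.0382; adjusted p = 0.913 with an estimated correlation).

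Hypoxia targets were higher in 7 of 27 and lower in 0 (10 adjusted over the list alone), with ADM at 0.83 ± 0.10 and LOX at 1.28 ± 0.17 (camera adjusted p = 0.00269; adjusted p = 0.727 with an estimated correlation). Basal genes were higher in 8 of 25 and lower in 2 (14 adjusted over the list alone), with EGFR at 0.53 ± 0.09 and KRT5 at 0.41 ± 0.08 (camera adjusted p = 0.00831; adjusted p = 0.843 with an estimated correlation). Suprabasal differentiation genes were higher in 6 of 51 and lower in 2 (13 adjusted over the list alone), with SCEL at 1.36 ± 0.07 and KLK7 at 1.29 ± 0.20 (camera adjusted p = 0.0175; adjusted p = 0.843 with an estimated correlation). No member of the cell cycle list was called in edgeR's test, nor when adjusted over the list alone. The lists for ATF4 and mitochondrial mRNAs were called with replicate as a block alone (camera adjusted p = 0.00393 down and 0.000572 up; without it 0.273 and 0.242; both adjusted p = 0.913 with an estimated correlation).

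In single contrasts the FA effect was called for 225 genes in WT (176 higher, 49 lower), 118 in KO (96 higher, 22 lower), 222 in wounded WT (170 higher, 52 lower) and 119 in wounded KO (106 higher, 13 lower). With replicate as a block the counts were 548 (333 higher, 215 lower), 301 (216 higher, 85 lower), 520 (342 higher, 178 lower) and 275 (212 higher, 63 lower), with a larger share of lower genes in each. FKBP5 led in each, at 5.80 ± 0.20, 4.20 ± 0.19, 5.95 ± 0.21 and 4.27 ± 0.19. SULT1E1 rose in WT by 5.43 ± 0.58 and in wounded WT by 5.72 ± 0.59. FGFR2, a growth factor receptor, was lower in each, between -0.99 ± 0.12 in WT and -1.03 ± 0.12 in wounded WT. ELL2 and the ligand gene KITLG were also lower in each, with KITLG at -0.98 ± 0.10 in WT and -0.66 ± 0.10 in KO. The other genes named were BIRC3, TGM2, HRASLS2, TMEM45B, BARX2, TLCD1, ENTPD7, KIAA1217 and EXT1 in WT, and PNLIPRP3, CAVIN2, ALDH1A1, OLR1, WWTR1, DCBLD2, KCTD12, SPRED2 and MIR205HG in KO.

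A call in one genotype and not in the other was not a tested difference; that difference has its own test further on. WT and KO shared 76 higher FA genes (0.772 expected from independent lists) and 11 lower (0.0492 expected), and 81 higher (0.823 expected) and 10 lower (0.0309 expected) after wounding. DESeq2 called 675, 355, 629 and 344 genes in the same 4 contrasts, and a fit of the compared groups alone called 19, 18, 3 and 34.

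The single FA counts were smaller without most libraries. In WT the count was 65 and 121 without vehicle replicates 1 and 2, and 72 without FA replicate 1. Without FA replicate 2 it was 241, of which 140 were higher and 101 lower. In KO it was 53 without either vehicle replicate, and 51 and 50 without FA replicates 1 and 2. In wounded WT it was 89 and 104 without the wounded replicates 1 and 2, and 110 and 95 without the wounded FA replicates 1 and 2; in wounded KO it was 40, 48, 52 and 63 in the same order. The count for the mean FA effect stayed between 1279 and 1891.

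Wounding gave no called gene at 24 h in edgeR's quasi-likelihood test, in WT, in KO or in the mean of 4 contrasts. The members of the wound-edge list with the smallest p are given as values: the keratin KRT6B was at 0.43 ± 0.13 and the integrin ITGB6 at 0.38 ± 0.14 (both adjusted p = 1). DDIT4 was at 0.06 ± 0.24 for the mean wound effect. At an unadjusted p under 0.05 in edgeR's test there were 326 genes in WT, 483 in KO and 707 in the mean. These were 1.489%, 2.206% and 3.229% of the tested genes, fewer than the 5% expected without any effect. They therefore give no sign of a wound effect. The mean had 1148 such genes with replicate as a block. DESeq2 called 4, 12 and 29, and limma 0 in each. With replicate as a block edgeR called 0, 0 and 5, all 5 higher and named after their values were seen: CEACAM6 (0.46 ± 0.06; adjusted p = 0.0348), MBOAT2 (0.42 ± 0.06), CDC42EP2 (2.29 ± 0.28), TPPP3 (0.96 ± 0.11) and ANTXR2 (0.67 ± 0.09).

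Among the lists, with 0 members called, camera put wound-edge genes up after wounding (37 genes; adjusted p = 0.000144; adjusted p = 0.966 with an estimated correlation) and cell cycle genes down (46 genes; adjusted p = 3.98e-06; adjusted p = 0.966 with an estimated correlation). It also put up other NF-kB pathway genes (adjusted p = 0.000888; adjusted p = 0.498 with an estimated correlation), immune markers (0.00179; adjusted p = 0.175 with an estimated correlation), histones, a sign of RNA quality (0.00282; adjusted p = 0.787 with an estimated correlation), and immediate early genes (0.00807; adjusted p = 0.966 with an estimated correlation). Mitochondrial mRNAs and interferon-stimulated genes were called down with replicate as a block alone (adjusted p = 0.000173 and 0.028; both adjusted p = 0.966 with an estimated correlation). Adjusted over the list alone, 0 members passed in each but 1 in the immune marker list, CD68 at 0.66 ± 0.14. In simulated counts of 21896 genes for the mean wound effect, edgeR recovered 41.8% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 80.3% of those changed 4-fold, and for WT alone 2.99%, 28.4% and 66.7%. Among 21666 unchanged genes in the same simulations, edgeR made 10 false calls for the mean and 3 for WT, DESeq2 51 and 36, and limma 13 and 16. The simulated libraries varied independently, whereas the real ones shared a shift by replicate number. The recovered shares and false calls therefore need not hold for the real wound tests. The scratch removes or borders only part of a cell layer, and the labels did not say what part of the harvested cells lay near it.

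In the mean of unwounded and wounded cells, a contrast added after the data were seen, edgeR's test called 1 gene, FKBP5, for a difference in FA response between KO and WT. The FA effect on FKBP5 was smaller in KO by 1.64 ± 0.17 on the log2 scale (adjusted p = 0.0135 in edgeR's test). FKBP5 was at 0.155 ± 0.013 FPKM in WT and 1.39 ± 0.13 FPKM in KO with vehicle, and at 8.34 ± 0.36 FPKM in WT and 24.9 ± 2.4 FPKM in KO with FA (SD, n = 2), so its level in KO was higher both without and with FA. The call was lost without KO replicate 2 (adjusted p = 0.0602), KO with FA replicate 1 (0.0742), WT replicate 2 (0.0608) or wounded WT with FA replicate 1 (0.0542), and limma on log2(FPKM + 1) gave 0.42 with an adjusted p of 0.84. The contrast held 6 genes with replicate as a block, 54 in DESeq2, 16 in limma and 8 with no filter on low counts. The other 5 with replicate as a block, named after their values were seen, were MMP15 (1.36 ± 0.17), PIAS1 (-0.62 ± 0.08), TCEAL4 (-0.63 ± 0.09), CDC42EP2 (-4.48 ± 0.56) and UBAP1L (-2.10 ± 0.29), each with an adjusted p of 0.0479 in edgeR's test.

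In the contrasts fixed beforehand, the unwounded difference called 2 genes in edgeR's test, both with a lower FA effect in KO. They were HNRNPUL2-BSCL2 (-14.8 ± 1.49) and UBAP1L (-3.75 ± 0.45), each with an adjusted p of 0.0318 and named after their values were seen. HNRNPUL2-BSCL2 is a readthrough gene that shares exons with its neighbours and is uncertain, and it was not called with replicate as a block (adjusted p = 0.114). The block called CDC42EP2 instead, beside UBAP1L, at -7.96 ± 0.92 (adjusted p = 0.0405; 0.361 without the block), also named after its values were seen. The difference among wounded cells, the difference of the wound effect between KO and WT, and the difference of the FA effect between wounded and unwounded cells each called 0 genes in edgeR's test. They had 444, 356 and 373 genes at an unadjusted p under 0.05. These were 2.028%, 1.626% and 1.704% of the tested genes, fewer than the 5% expected without any effect. DESeq2 called 7, 14 and 11 genes there and limma 2, 0 and 0. The count for the unwounded difference was 0 without KO with FA replicate 1 and 5 without WT with FA replicate 1. HNRNPUL2-BSCL2 and UBAP1L kept their sign without each of the 8 libraries, but both stayed called only without WT with FA replicate 1. Without KO replicates 1 and 2 the adjusted p of edgeR's test was 0.0967 and 0.0912 for HNRNPUL2-BSCL2, and 0.0967 and 0.076 for UBAP1L. Without KO with FA replicates 1 and 2 it was 0.203 and 0.35 for either gene. Without WT replicates 1 and 2 it was 0.36 and 0.218 for HNRNPUL2-BSCL2, and 0.313 and 0.108 for UBAP1L. Without WT with FA replicate 2 it was 0.08 for HNRNPUL2-BSCL2 and 0.113 for UBAP1L. HNRNPUL2-BSCL2 was also not called in limma (0.11) or with no filter on low counts (0.193), and UBAP1L was not called in a fit of the compared groups alone (0.167). DDIT4 was not called in any difference.

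The genes called for the mean FA effect moved in the same direction in both genotypes in 1852 of 1857 cases (99.7%), with a Pearson correlation of 0.827 across genes, which are not independent replicates. Glucocorticoid receptor targets had a smaller FA effect in KO in camera, with 1 of 28 members called, FKBP5 itself, and 2 adjusted over the list alone. The camera adjusted p was 8.7e-06, and 0.11 with an estimated correlation. Cytokines had a less negative FA effect in KO, with 0 of 19 called and 0 adjusted over the list alone. Their camera adjusted p was 0.0124, and 0.966 with an estimated correlation. The metallothionein list had a lower FA effect in KO, with 0 of 6 members called and 0 adjusted over the list alone. Its camera adjusted p was 0.023, and 0.966 with an estimated correlation. The PI3K-AKT-mTOR list also had a lower FA effect in KO, with FKBP5 again the 1 called member and 1 adjusted over the list alone. For that list the camera adjusted p was 0.016, and 0.11 with an estimated correlation.

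**Figure D3:**
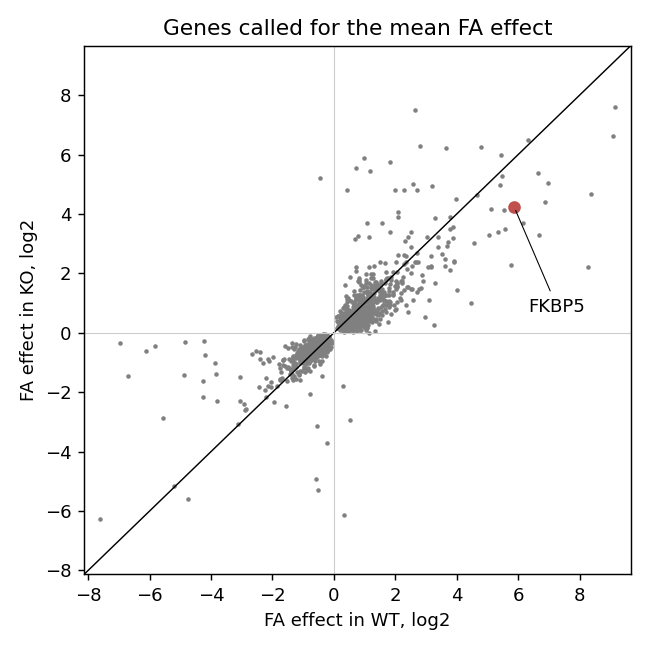
FA effect in KO (vertical, log2) against that in WT (horizontal, log2), each the mean of unwounded and wounded cells, for the 1857 genes called for the mean FA effect; each dot is a gene, the line marks equal effects and FKBP5 is in red. Of the genes, 1852 had the same sign in both; they were selected for a mean effect, which favours equal signs.

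The differences between KO and WT were arranged along the chromosomes, a feature examined after the data were seen. In 137 windows of 20 Mb with at least 15 genes of at least 3 FPKM, the median log2 difference over the genes was -0.47 in the first 20 Mb of chromosome 1 and -0.51 between 40 and 60 Mb of chromosome 22. It was 0.62 in the first 20 Mb of chromosome 2, 0.53 and 0.57 in the first 2 windows of chromosome 12, and 0.52 in the first 20 Mb of chromosome 18. The SD of the window medians was 0.223, against at most 0.102 in 1000 permutations of the genes' positions. For the mean FA effect, a contrast within the cell lines, the SD was 0.0389 against at most 0.0359. Exceeding the permutations was therefore not particular to KO against WT, though the SD and its distance from the permutations were larger there.

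**Figure D4:**
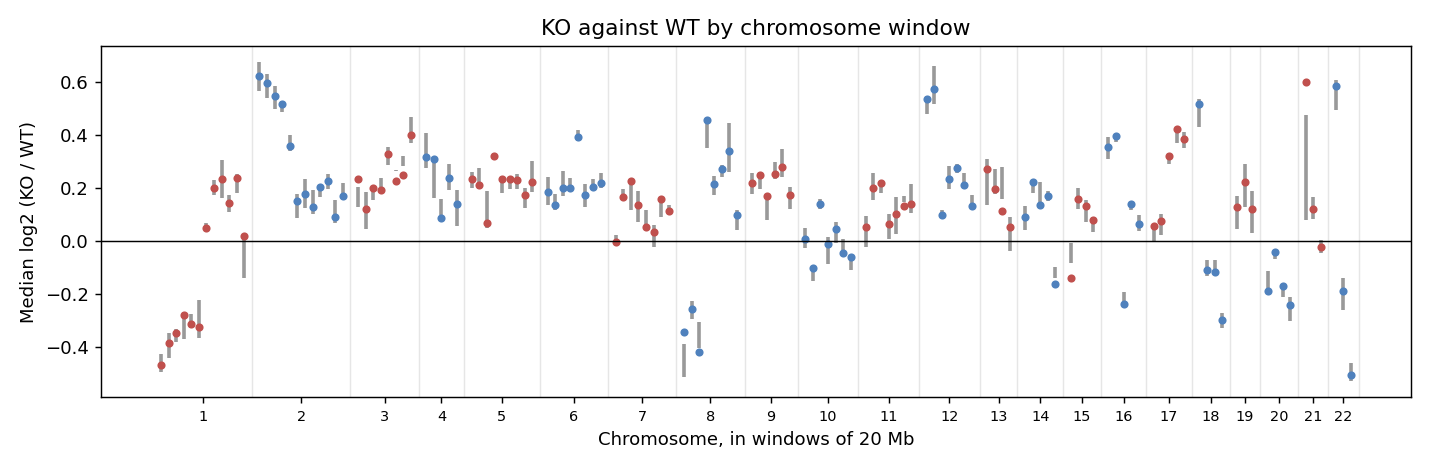
Median log2 difference of KO from WT (vertical) over the genes of each 20 Mb window along chromosomes 1 to 22 (horizontal); dots are medians of the mean over the 4 treatments, and grey bars run from the lowest to the highest median of the single treatments. In 26 of 137 windows the dot lies outside its bar, since a median of means need not lie between medians; the first window of chromosome 21, with 18 genes, includes ribosomal RNA copies.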

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

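The contrast of the mean difference in FA effect, behind the FKBP5 result, was added after the data were seen. The tests chosen only after the result was seen included the correlation of chromosome windows between treatments. They also included the tests of a ceiling and of counting error for FKBP5, and the comparison with sampling for genes at 0.

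FKBP5 had an FA effect that differed between KO and WT in a test of the difference itself, at -1.64 ± 0.17 (adjusted p = 0.0135 in edgeR's test; 0.00859 with replicate as a block). A ceiling shared by both genotypes was excluded, since FKBP5 with FA was higher in KO by 1.52 ± 0.12. The lowest FKBP5 count in WT without FA was 96, which missed the bound set beforehand for excluding too few counts. The 95% interval of counting error reached 0.136 to either side of the difference on the log2 scale, less than the difference itself. FKBP5 was chosen for passing a test with a standard error of 0.17, already above that width. The comparison with counting error could therefore hardly have come out otherwise and was no separate test. A smaller FA response in general was left open: over 1856 other FA genes the median difference, signed by the FA effect, was -0.0949, and limma's rotation test fry missed its threshold of 0.05. A higher level without FA in KO, by 3.16 ± 0.13, may account for the smaller fold, and no test here told loss of REDD1 from another difference between the cell lines.

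Genes of whole chromosome regions differed between KO and WT, with an SD of window medians of 0.223. GC content, length and level of the genes were excluded as the whole cause, with an SD of 0.216 after correction against at most 0.104 in permutations. The pattern remained in the 7159 genes changed under 2-fold, with an SD of 0.205 against at most 0.0945. A window median hardly depends on a few genes, so this could hardly have come out otherwise. Window medians from separate libraries of the 4 treatments correlated by at least 0.958 over windows of genes, which are not independent replicates. Any lasting difference between the cell lines would give such a correlation. It therefore did not test for copy number or another regional difference between the cell lines. DNA was not analysed here, so which of these applies, and how many KO differences were unrelated to REDD1, stayed open.

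There were 136 genes, 0.621% of those tested, at 0 in 1 library and over 100 counts in the other library of a group. Of these, 56% overlapped an exon of another gene on the same strand, against 16.3% of genes at the same level, a ratio of 3.43. This is consistent with reads being assigned to one overlapping gene or another. From the other library and the totals, at least 75.7 counts were expected at each zero, above the 3 counts that a 0 allows. The choice of genes with over 100 counts fixed this outcome, since totals had ratios of 0.728 to 0.892. It was therefore no separate test of sampling at a lower depth. Of the 285 zeros, 74.4% were in replicate 1, and what set replicate 1 apart was left open, since replicate number and depth went together; no biological explanation was tested.

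HNRNPUL2-BSCL2 differed in its FA effect between unwounded KO and WT at -14.8 ± 1.49 (adjusted p = 0.0318 in edgeR's test; 0.114 with replicate as a block), a fitted value; its counts of 4186 in KO and 0 in KO with FA made it at least 1350-fold lower against a floor of 3 counts over the group, while in wounded KO its counts were 1012 and 610 without FA and 2671 and 2957 with FA. UBAP1L differed at -3.75 ± 0.45 (adjusted p = 0.0318; 0.0405 with replicate as a block), with 242 and 276 counts in KO and 18 and 19 in KO with FA, but 149 and 278 in wounded KO and 260 and 219 in wounded KO with FA. Neither gene stayed called when a KO library, a KO library with FA, a WT library or WT with FA replicate 2 was left out (adjusted p from 0.08 to 0.36 for HNRNPUL2-BSCL2 and from 0.076 to 0.35 for UBAP1L).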

How the results depend on the processing

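Tests added after the results were seen were those of the mean difference in FA effect and of the mean difference in wound effect between KO and WT, under each alternative. Of 346 gene changes named by the rule and called, 345 kept their sign in each alternative run, 313 stayed called in each alternative other than leaving out libraries and fitting the compared groups alone, and 267 stayed called without each library. A gene that an alternative did not test was not counted against it, so the 345 and 313 are upper bounds. Limma tested 122 of the 136 named genes for KO against WT in the mean of 4. DESeq2 size factors in edgeR moved no count of genes by over 1.5 times. A smaller FPKM pseudocount, no filter on FPKM and quantile scaling were set for the case that FPKM alone was given, and were not run; limma on log2(FPKM + 1) was run.

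With replicate as a block, edgeR's counts became 5330 for KO against WT with vehicle, 548, 301, 520 and 275 for FA in WT, KO, wounded WT and wounded KO, 3015 for the mean FA effect, 5 for the mean wound effect and 6 for the mean difference in FA effect. With DESeq2 they became 675, 355, 629 and 344 for FA in the same 4 contrasts, and 4, 12 and 29 for wounding in WT, in KO and in the mean. For differences DESeq2 called 15 genes for FA in unwounded and 7 in wounded cells, 14 for wounding, 11 for FA in wounded against unwounded cells, 54 for the mean difference in FA effect and 14 for that in wound effect. Limma called 77 for FA in wounded KO, 4 and 2 for the unwounded and wounded differences in FA effect, and 16 for their mean. With no filter edgeR called 1 for wounding in KO, 2 in the mean, 2 for the wounded difference in FA effect, 1 for the difference in wound effect, 1 for FA in wounded against unwounded cells and 8 for the mean difference in FA effect. The cause was not tested.

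With the compared groups alone, fits with fewer samples, the counts were 980, 860 and 3127 for KO against WT with vehicle, wound and wound with FA, 19, 18, 3 and 34 for FA in WT, KO, wounded WT and wounded KO, 2 for wounding in WT, 1 for the unwounded difference in FA effect and 3 for the difference in wound effect. With an estimated correlation camera called 0 lists for KO, 4 for FA and 0 for wounding.

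Without single libraries, the counts for KO against WT ran from 1474 to 3052 with vehicle, 2157 to 2830 with FA, 1662 to 3147 after wounding and 2170 to 3100 after both. Those for FA ran from 65 to 241 in WT, 50 to 53 in KO, 89 to 110 in wounded WT and 40 to 63 in wounded KO. Those for wounding ran from 0 to 3 in WT, 1 to 3 in KO and 0 to 3 in the mean. For differences they ran from 0 to 5 for FA in unwounded and 0 to 4 in wounded cells, 0 to 3 for wounding, 0 to 2 for FA in wounded against unwounded cells, 0 to 4 for the mean difference in FA effect and 0 to 3 for that in wound effect.

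Signs reversed for FKBP5 and DDIT4. The mean difference in FA effect on FKBP5 was 0.42 in limma on log2(FPKM + 1), where 1 FPKM exceeds the WT level without FA, and ran from -1.83 to -1.48 without single libraries. DDIT4, called in none of these, ran without single libraries from -0.33 to 0.92 for wounding in WT, -0.53 to 0.56 in KO and -0.0776 to 0.25 in the mean. Its differences ran from -1.07 to 0.21 for FA in unwounded and -0.54 to 0.51 in wounded cells, -0.89 to 0.38 for wounding, -0.46 to 0.20 for FA in wounded against unwounded cells, -0.56 to 0.10 for the mean difference in FA effect and -0.38 to 0.25 for that in wound effect. The last was 0.00405 with no filter.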

Other observations

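The tests of gene ontology terms, and the splits of the samples for the wound effect, were chosen only after the results were seen.

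With FA, some genes of ribosome production were called lower, though most members of either term did not pass. Of 88 genes of ribosome biogenesis 37 were lower and 0 higher (camera adjusted p = 6.74e-12 over 1070 terms; adjusted p = 0.998 with an estimated correlation), and of 147 genes of rRNA processing 48 were lower and 0 higher (adjusted p = 6.74e-12; adjusted p = 0.998 with an estimated correlation).

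In KO, 70 of 87 genes of mitochondrial translational elongation were higher and 2 lower (camera adjusted p = 1.18e-09; adjusted p = 0.75 with an estimated correlation), while mitochondrially encoded mRNAs were lower in 4 of 13. DNA replication genes were higher in 86 of 134 and lower in 14 (adjusted p = 7.39e-07; adjusted p = 0.75 with an estimated correlation), and basement membrane genes lower in 31 of 62 and higher in 5 (adjusted p = 1.57e-05; adjusted p = 0.75 with an estimated correlation).

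Other splits of the samples that part every pair with equal replicate numbers were drawn, 59 beside the real one. For KO against WT, only the real one of the 60 splits gave as many as 10599 genes. The highest other gave 6466, in a split that kept 7 of the 8 pairs as they were. That makes a chance split of these libraries unlikely. It does not tell loss of REDD1 from another difference between the cell lines. For FA, only the real one of the 60 splits gave as many as 1857 genes, with 245 in the highest other, so a chance split was unlikely there too. For wounding the real count was 0, which all 60 of the 60 splits must reach (highest other 1), so the splits decide nothing there. These splits used the model with 8 group means, which was taken after an additive model had been run, because it gives the reported counts; the additive model gave 11097 against 6598 for KO, 2482 against 1 for FA and 1 against 0 for wounding.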
